A study of Mus musculus with 8 samples.

How the data were processed

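Gene expression was measured in distal convoluted tubules (DCT), the nephron segment after the thick ascending limb, from kidneys of male C57/Bl6 mice aged 8 weeks. The mice carried EGFP under the parvalbumin promoter, which marks the early DCT, and per the labels' protocols the fluorescent tubules were collected on a large-particle sorter (COPAS). Labelled cDNA was made from 100 ng of RNA, and each of the 8 samples was read on its own 1-colour Affymetrix array with a biotin label. Samples were assigned to TBC1D4-deficient (4) or wild-type (4) by their titles.

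The authors deposited probe set intensities on a linear scale, 1 column per sample, with 28371 probe sets. Per the submitters' processing notes, Affymetrix Power Tools was used. Its version, the summarisation and the normalization between arrays are not given in the sources used here. The quartiles of the 8 columns were nearly the same, with medians of 8.41 to 9.03, so the arrays had already been brought to a common scale. If that step forced equal distributions, a change shared by most genes would be hidden. The table holds no detection call, so a low intensity cannot be told from background, and a fold change of a dim gene can be understated. For arrays, the number of arrays per group (4) limits the precision.

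The values proved to be linear, so log2 was taken before any test, with no pseudocount, no further normalization and no filter. The genotypes were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 2-sided, no covariate) over 23039 probe sets paired with at least 1 gene symbol, with Benjamini-Hochberg adjustment and a threshold of 0.05. Of all probe sets, 21158 had exactly 1 symbol, 1881 had several and 5332 had none in the platform annotation. No gene is named from a probe set with several symbols. Gene identifiers of 21128 probe sets with 1 symbol matched the mouse RefSeq gene table (GRCm38.p6), which updated 0 symbols. That table was used for names, chromosomes and the order of neighbouring genes, and no coordinates are given because the build behind the array annotation is not given in the sources used here. Intervals are 95% confidence intervals from the limma fit.

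A total of 28 gene lists were fixed before the data were examined. They covered DCT transport, glucose handling, insulin signalling, Rab GTPases and their regulators, metabolism, cell state, and markers of 9 other cell types. Of their 634 symbols, 574 were measured, each gene by its brightest probe set of 1 symbol, over 18782 genes. Each list was tested against all other genes with camera (preset correlation 0.01), with Benjamini-Hochberg adjustment over the 28 lists, and then with an estimated correlation and with fry. The mean of each marker list per array, each gene centred on its mean over the 8 arrays, was compared by an exact 2-sided permutation test over all 70 assignments of arrays, whose smallest possible p is 0.0286. Genes within 10 Mb of Tbc1d4 were compared with all other genes by Fisher's exact test and camera.

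The genes named were also set by a rule fixed before the data were examined. They are Tbc1d4 and 9 genes of DCT function and glucose transport; the genes past the threshold, filled up to 20 by the smallest unadjusted p, without predicted genes, olfactory and vomeronasal receptors, small RNAs and Riken clones; and up to 4 members with the smallest p of each list described. Genes outside the rule are marked where they appear, as picked after their values were seen.

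The scripts were tested on simulated data built from the means and spread of these arrays. With a small set of the 23039 probe sets, drawn from those above the median level, changed together, 76.8% of 1.5-fold changes, 94.8% of 2-fold changes and 98% of 3-fold changes passed the threshold. For a gene changed alone the shares were 23.6%, 72.4% and 92.4%. A change of 0.32 on the log2 scale passed in 32.4% when changed together and in 0.4% alone, so a single change of that size would nearly always be missed. In the list test, a shift of 0.2 on the log2 scale in the glycolysis list was called in 20 of 20 draws, and 4 of 540 unchanged lists were called. That noise was drawn independently for each gene, so these shares do not hold for lists whose members vary together between arrays.

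The alternatives were filters on dim probe sets, other sets of rows, renewed normalization, another eBayes prior, array weights, blocks or covariates from numbers in the labels, other thresholds, other list settings, other windows around Tbc1d4, and leaving out each array in turn. One covariate, the identifier range, used a second number of unstated meaning in the descriptions. It was 3204 to 3208 in TBC1D4-deficient replicates 1, 3 and 4 and wild-type replicate 2, and 3252 to 3256 in the other arrays. That range is unbalanced between genotypes, so its effect and that of genotype cannot be fully separated. Added after the data were examined were the proximal tubule marker mean as a covariate and a split of the arrays by the first number of their descriptions.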

Results

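The data were 8 arrays of sorted mouse DCT, 4 from TBC1D4-deficient and 4 from wild-type mice. TBC1D4 (AS160) is a Rab GTPase-activating protein that restrains the movement of GLUT4 vesicles to the plasma membrane until insulin signalling phosphorylates it. The comparison between genotypes addresses which genes of the DCT change when TBC1D4 is missing and whether any of them compensates for it. Pearson correlations between arrays on the log2 scale ran from 0.993 to 0.997, with a mean of 0.995 within a genotype and 0.996 between genotypes, and no pair of arrays held identical values. The labels name separate samples without stating that each came from its own animal, so p-values measure the spread between these samples. The sample descriptions open with numbers from 5 to 12 of unstated meaning; those numbered 5 to 8 and 9 to 12 hold 2 arrays of each genotype apiece, and values within each of these number sets are given because the arrays differed between them.

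Tbc1d4 was 19.3-fold lower in the TBC1D4-deficient tubules (95% interval 16.3 to 22.9). Its probe set (10422028, chromosome 14) averaged 6.75 ± 0.15 on the log2 scale in wild-type arrays (SD, n = 4) and 2.48 ± 0.21 in TBC1D4-deficient arrays (SD, n = 4). The intensities were 95.6 to 122.8 in the wild-type arrays and 4.64 to 6.59 in the TBC1D4-deficient arrays, so every array matched its label. The TBC1D4-deficient level cannot be told from background, and if it is background the fold is a lower bound. The log2 difference was -4.27 (SE 0.11), with a limma adjusted p of 6.35e-08. An exact permutation test gave p = 0.0286, the smallest it can give with 4 arrays against 4. Within the sets numbered 5 to 8 and 9 to 12 the log2 difference was -4.33 and -4.21. Which part of the gene was deleted, and which exons the probe set reads, are not given in the sources used here.

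**Figure D1:**
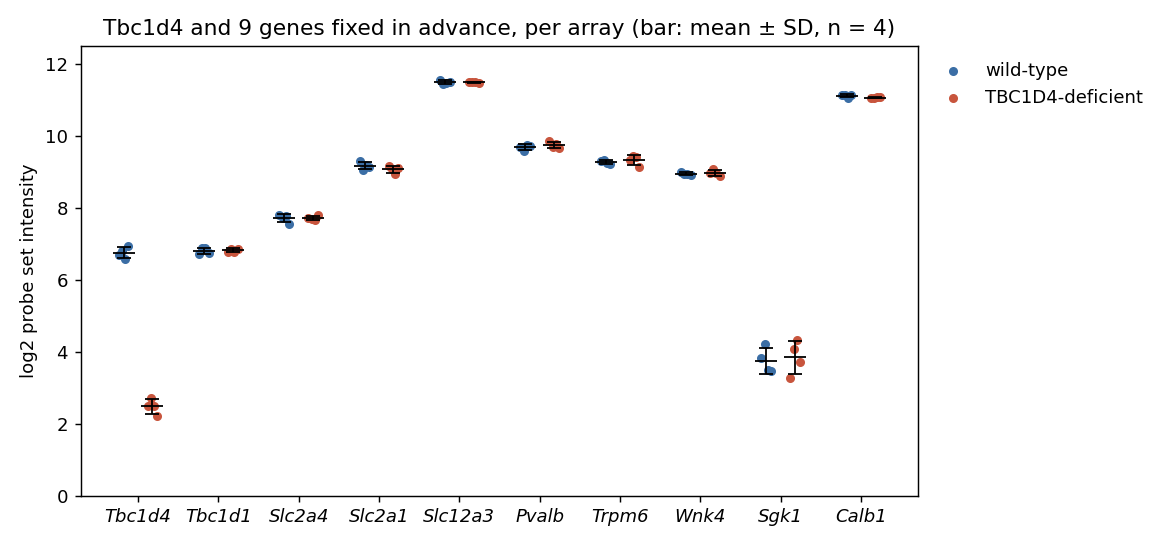
The log2 probe set intensity (vertical axis) of Tbc1d4 and 9 genes fixed in advance is plotted for the 4 wild-type arrays (blue) and the 4 TBC1D4-deficient arrays (red), with points for arrays and bars for the mean ± SD. Tbc1d4 lies at 6.58 to 6.94 in wild-type and 2.21 to 2.72 in TBC1D4-deficient arrays, and for the 9 other genes the groups overlap.

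No gene other than Tbc1d4 passed the threshold. Of 23039 probe sets, 1 was lower and 0 were higher at a limma adjusted p below 0.05, and the smallest adjusted p of any other probe set was 0.9999. An unadjusted p below 0.05 was found for 667 probe sets (2.9%), of which 327 were higher and 340 lower in the TBC1D4-deficient tubules. The groups did not overlap in 426 probe sets (1.85%), against 2.86% by chance. The 95% interval of the difference lay inside 1.5-fold for 97.4% of the probe sets. Only 20 probe sets differed by 1.5-fold or more, and of these Tbc1d4 alone passed the threshold. Tbc1d4 was also the only call within either number set and with the set as a covariate.

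The 19 other genes with the smallest unadjusted p had log2 differences of 0.21 to 0.54 in size, with 7 higher and 12 lower in the TBC1D4-deficient tubules, and none passed after adjustment (limma adjusted p = 0.9999). The smallest unadjusted p, 0.000176, belonged to Commd6, a member of the COMMD family that takes part in endosomal sorting, at 7.77 ± 0.09 against 7.40 ± 0.04 in wild-type (log2 difference 0.36, 95% interval 0.22 to 0.50). Dpysl2, a regulator of microtubule assembly, had a log2 difference of -0.32 (-0.46 to -0.19). Pxmp2, a peroxisomal membrane channel, stood at 0.37 (0.19 to 0.55). Phf23 and Mrm3, a mitochondrial rRNA methyltransferase, stood at 0.36 and 0.42, and Gskip and Mthfd2, a mitochondrial enzyme of folate metabolism, at 0.27 and 0.21. Differences of -0.54, -0.45 and -0.37 were measured for Ptprb, a receptor phosphatase of endothelium, Irx3, a transcription factor of nephron segmentation, and Heg1, a receptor needed for vessel integrity. A dimmer probe set of Irx3 stood at 0.12, and of Heg1 at -0.15. Zcchc3 and Ankrd61 stood at -0.41 and -0.35. Dipk1a and Pde2a, a cyclic nucleotide phosphodiesterase, stood at -0.23 and -0.24. The others were Krtap10-10 (0.31), Wap (-0.30), Cysltr1 (-0.27), Ang4 (-0.26) and Ifnlr1 (-0.25). All of these were dim, at 2.29 to 3.50 in wild-type arrays. So were Ankrd61, Zcchc3, Pde2a, Gskip, Pxmp2, Phf23 and Heg1, at 2.40 to 3.65. Ptprb, Mrm3, Mthfd2 and Irx3 were little brighter, at 4.10 to 4.41.

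**Figure D2:**
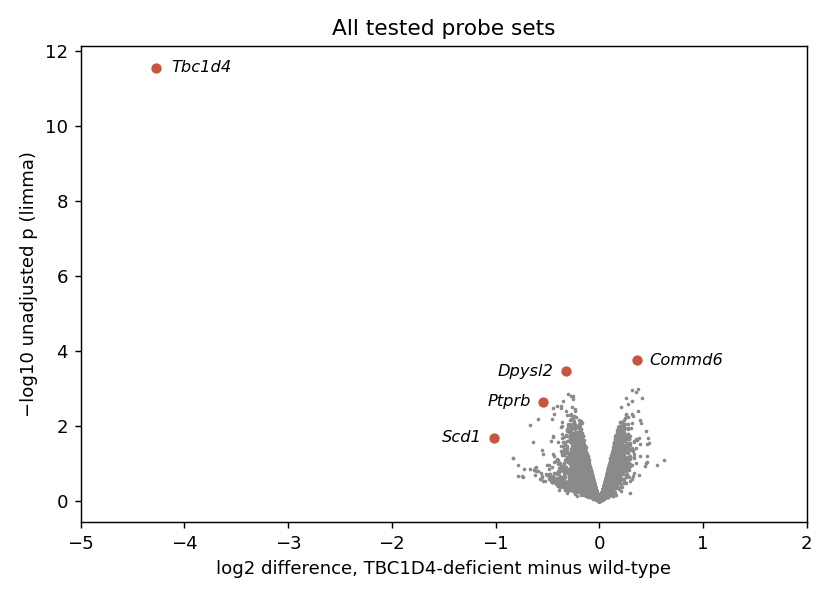
Each point is 1 of 23039 probe sets, with the log2 difference (TBC1D4-deficient minus wild-type) on the horizontal axis and the negative log10 of the unadjusted limma p on the vertical axis. Tbc1d4 stands alone at -4.27; Commd6, Dpysl2, Ptprb and Scd1 are marked and did not pass the threshold after adjustment.

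The transporters that define the DCT differed little between genotypes. Slc12a3, the thiazide-sensitive sodium chloride cotransporter, averaged 11.49 in both groups (log2 difference -0.0025, 95% interval -0.12 to 0.12). That is close to the brightest probe set of each array (intensities of 3915 to 4138), where differences can be compressed. Pvalb, the calcium-binding protein whose promoter marked the sorted tubules, had a difference of 0.06 (-0.09 to 0.21), and Wnk4, a kinase that regulates the cotransporter, of 0.02 (-0.11 to 0.16). Of 14 measured genes of sodium transport and its kinases, 8 lay above and 6 below 0, 0 passed (over all probe sets or adjusted over the list alone), and the interval lay inside 1.5-fold for 13. Kcnj10 and Kcnj16, subunits of the basolateral potassium channel, stood at 0.07 and 0.03, Cul3, the scaffold of the ubiquitin ligase that targets WNK kinases, at -0.08, and Bsnd, a chloride channel subunit, at 0.05. The list had a camera adjusted p of 0.891, and of 0.925 with an estimated correlation.

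Genes of calcium and magnesium handling were likewise spread around 0, with 8 above and 9 below, all 17 inside 1.5-fold and 0 past the threshold in either adjustment (camera adjusted p = 0.975). Trpm6, the magnesium channel of the DCT, had a log2 difference of 0.05 (-0.12 to 0.22), and Calb1, a cytosolic calcium-binding protein, of -0.05 (-0.17 to 0.07). Atp2b4, a plasma membrane calcium pump, stood at 0.12 (-0.10 to 0.33) and Trpv5, a calcium channel, at -0.12 (-0.35 to 0.12). Targets of aldosterone and glucocorticoids numbered 10 above and 8 below 0 of 18, with 10 inside 1.5-fold, 0 past the threshold in either adjustment and a camera adjusted p of 0.448. That list was called in 1 of 25 alternative settings, without wild-type replicate 2 (0.105, adjusted p = 0.0253). Their 4 smallest p-values belonged to Tsc22d3 (GILZ) at 0.32 (0.02 to 0.61), Usp2 at 0.33 (-0.03 to 0.70), Fkbp5 at 0.29 (-0.03 to 0.61) and Scnn1a, a subunit of the epithelial sodium channel, at 0.14 (-0.02 to 0.29). Sgk1, a kinase induced by aldosterone, was dim and varied between arrays (log2 difference 0.10, -0.40 to 0.60).

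Candidate compensation among relatives and partners of TBC1D4 was examined in 5 lists, and 0 of their members passed over all probe sets or adjusted over the list alone. Tbc1d1, the closest paralog of Tbc1d4, averaged 6.81 ± 0.09 in wild-type and 6.82 ± 0.05 in TBC1D4-deficient arrays (SD, n = 4 each), a log2 difference of 0.02 (95% interval -0.13 to 0.16). Of 38 Rab GTPase-activating proteins with a TBC domain, a list that holds Tbc1d1 but not Tbc1d4, 20 lay above and 18 below 0, and 37 were inside 1.5-fold (camera adjusted p = 0.817). Sgsm3 stood at 0.18 (0.04 to 0.33), Tbc1d31 at 0.18 (0.00331 to 0.36), Tbc1d10a at 0.19 and Tbc1d23 at -0.17. Of 42 Rab GTPases, 16 lay above and 26 below 0, and all 42 were inside 1.5-fold (camera adjusted p = 0.891). Rab27a, which acts in secretion, stood at 0.14 and Rab5c, of early endosomes, at -0.10, with Rab38 at 0.10 and Rab6b at -0.12. Rab38 was dim, at 3.57 in wild-type arrays.

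Slc2a4 (GLUT4), the glucose transporter that TBC1D4 regulates in muscle and fat, had a log2 difference of 0.0047 (-0.15 to 0.16), and Slc2a1 (GLUT1) of -0.10 (-0.27 to 0.06). Among 13 glucose transporters, 6 lay above and 7 below 0, and only 9 were inside 1.5-fold (camera adjusted p = 0.891). The smallest unadjusted p among them was 0.0238, for Slc2a9, a urate transporter of the GLUT family, at 0.24 (0.04 to 0.43). Slc2a8 stood at 0.09 and Slc2a10, which was dim (1.73 in wild-type arrays), at -0.12. In GLUT4 vesicle traffic, 14 lay above and 9 below 0, and all 23 were inside 1.5-fold (camera adjusted p = 0.898). Cdc42 stood at -0.17 (-0.30 to -0.04) and Exoc3, an exocyst subunit, at 0.15 (0.0063 to 0.30), with Snap23 at -0.11 and Trip10 at 0.09. In insulin, Akt and AMPK signalling, 14 lay above and 16 below 0, and all 30 were inside 1.5-fold. That list had a mean of 0.0147, a median of -0.0044 and a camera adjusted p of 0.633. Prkab2, a subunit of AMPK, stood at -0.13 and Tsc1, a brake on mTORC1, at 0.14, with Trib3 at 0.22 and Pik3r2 at 0.11. Prkab2 and Trib3 were dim, at 4.117 and 2.795 in wild-type arrays.

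Small shifts of whole lists were found in energy metabolism and the cell cycle, and each call was lost with an estimated correlation. With fry, 0 of the 28 lists passed (smallest adjusted p = 0.77). With the preset correlation 8 lists passed by genotype. Other splits of the 8 arrays into 4 and 4 gave a median of 5 (0 to 9). Of 48 genes of oxidative phosphorylation, 39 were higher in the TBC1D4-deficient tubules, by a mean of 0.055 on the log2 scale, with all 48 inside 1.5-fold (camera adjusted p = 6.22e-05; adjusted p = 0.588 with an estimated correlation). The complex I subunits Ndufb10 and Ndufs1 stood at 0.19 and 0.12, Ndufa4 at 0.15 and Cox5a, of complex IV, at 0.15. The mean was 0.085 within the arrays numbered 5 to 8 and 0.025 within 9 to 12 (adjusted p = 0.5 in the latter). Of 28 genes of fatty acid oxidation and other PPARA targets, 24 were higher, by a mean of 0.039, with 25 inside 1.5-fold (camera adjusted p = 0.0174; adjusted p = 0.852 with an estimated correlation). Acaa1a and Acadl, enzymes of beta oxidation, stood at 0.12 each, with Etfa, an electron carrier, at 0.12 and the carnitine carrier Slc25a20 at 0.15. This call ended without TBC1D4-deficient replicate 2 (0.0109, adjusted p = 0.0899) or 3 (0.0182, adjusted p = 0.256) and without wild-type replicate 1 (-0.00112, adjusted p = 0.404) or 2 (0.0139, adjusted p = 0.117), and within arrays 9 to 12 (0.00289, against 0.0753 within 5 to 8). The mean was 0.0771 without TBC1D4-deficient replicate 1 and 0.0937 without wild-type replicate 4. It was 0.0874 with the proximal tubule marker mean as a covariate (adjusted p = 0.00013), 0.0925 with the identifier range (adjusted p = 0.0082) and 0.0596 with each array centred on its median (adjusted p = 0.0179). The list means of wild-type replicates 1 and 4 and TBC1D4-deficient replicate 1 were -0.14, 0.144 and -0.0944, beside -0.465, 0.685 and -1.04 for the proximal tubule markers.

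Of 25 cell cycle genes, 22 were higher in the TBC1D4-deficient tubules, by a mean of 0.13, with 20 inside 1.5-fold (camera adjusted p = 2.14e-05; adjusted p = 0.588 with an estimated correlation). Ccnb2, a mitotic cyclin, stood at 0.33 (0.0085 to 0.65), Top2a, a DNA topoisomerase of dividing cells, at 0.31 (0.0095 to 0.61), Birc5 (survivin) at 0.16 and Ccnd1, a G1 cyclin, at 0.13. Ccnb2, Top2a and Birc5 were dim, at 4.14, 3.07 and 2.41 in wild-type arrays, and the other probe sets of Top2a, dimmer still, stood at -0.08 and 0.05. The shift lay in TBC1D4-deficient replicates 3 and 4, whose list means were 0.226 and 0.25 against -0.101 and -0.106 in replicates 1 and 2. It was 0.279 within arrays 5 to 8 and -0.0102 within 9 to 12, where the call was lost (adjusted p = 0.946). The mean dropped to 0.0812 without TBC1D4-deficient replicate 3, 0.0734 without replicate 4 and 0.088 without wild-type replicate 1, and the call was lost with the identifier range in the labels as a covariate (0.0664, adjusted p = 0.0673). In none of these 3 lists did a member pass over all probe sets or adjusted over the list alone.

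With all 8 arrays and the preset correlation, no shift was called in 8 other lists of metabolism and cell state, and 0 of their members passed in either adjustment. Camera adjusted p was 0.644 for glycolysis (14 above, 8 below 0), 0.975 for gluconeogenesis and glycogen (8 above, 9 below), 0.755 for cholesterol and fatty acid synthesis (8 above, 12 below) and 0.667 for the circadian clock (10 above, 6 below). For gluconeogenesis and glycogen the mean (-0.0226) and median (-0.0284) were negative while the test pointed up. The adjusted p was 0.149 for immediate early and dissociation stress genes (6 above, 17 below), 0.898 for heat shock and the unfolded protein response (7 above, 14 below), 0.0986 for the interferon response (6 above, 20 below) and 0.891 for tubular injury (8 above, 10 below). Among 25 alternative settings, calls appeared in 5 for the immediate early list (lowest adjusted p = 3.42e-05), 5 for interferon (0.0115), 4 for cholesterol and fatty acid synthesis (8.14e-05), 1 for the clock and 1 for heat shock. Within arrays 5 to 8 and 9 to 12 the mean was 0.117 and -0.328 for the immediate early list and -0.208 and 0.0729 for cholesterol and fatty acid synthesis, so these lists cannot be called unchanged. Scd1, a fatty acid desaturase of the synthesis list that was picked after its values were seen, stood at -1.01 (95% interval -1.84 to -0.19; limma adjusted p = 0.9999).

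Markers of other cell types that sorted tubules can carry gave shifts in 5 of 9 lists. All 13 endothelial markers were lower in the TBC1D4-deficient tubules, by a mean of 0.26 (log2 difference -0.264; camera adjusted p = 1.82e-10; adjusted p = 0.392 with an estimated correlation). Adjusted over the list alone, 3 of the 13 passed and over all probe sets 0 did. These were Ptprb at -0.54 (-0.84 to -0.24), Emcn, an endothelial sialomucin, at -0.46 (-0.75 to -0.16) and Tek, the angiopoietin receptor, at -0.30 (-0.51 to -0.09), and Pecam1 stood at -0.35. Ptprb, Tek and Pecam1 were dim, at 4.10, 3.20 and 3.41 in wild-type arrays. The mean of the list was lower in each TBC1D4-deficient array than in any wild-type array. An exact permutation test gave p = 0.0286, the smallest possible, and 0.257 after adjustment over 9 lists. The list mean was -0.377, -0.00551, 0.00579 and -0.152 in TBC1D4-deficient replicates 1 to 4. In wild-type replicates 1 to 4 it was 0.132, 0.025, 0.19 and 0.181, so TBC1D4-deficient replicates 2 and 3 lay close to wild-type replicate 2. Within arrays 5 to 8 and 9 to 12 the mean difference was -0.181 and -0.348.

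Markers of the proximal tubule, the most abundant tubule of the cortex, were lower for all 19 genes by a mean log2 difference of -0.303 (camera adjusted p = 0.00155; adjusted p = 0.925 with an estimated correlation). The arrays overlapped, from -1.04 in TBC1D4-deficient replicate 1 to 0.691 in wild-type replicate 3 (exact permutation p = 0.486). Gatm, an enzyme of creatine synthesis, averaged 8.02 ± 1.02 in wild-type and 7.48 ± 0.81 in TBC1D4-deficient arrays (SD, n = 4 each), Cubn, an endocytic receptor, 6.18 ± 0.86 and 5.63 ± 0.67, Slc22a8, an organic anion transporter, 7.05 ± 0.59 and 6.71 ± 0.48, and Fut9 4.52 ± 0.72 and 4.09 ± 0.56. The call was lost without TBC1D4-deficient replicate 1 (-0.00792, adjusted p = 0.963), without wild-type replicate 3 (-0.123, adjusted p = 0.377) or 4 (-0.125, adjusted p = 0.327), with the identifier range as a covariate (-0.00384) and within arrays 5 to 8 (-0.122, against -0.484 within 9 to 12). The mean difference was -0.509 without wild-type replicate 1 and -0.455 without replicate 2.

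Markers of connecting tubule and principal cells were lower in 12 of 13 genes, by a mean log2 difference of -0.131 (camera adjusted p = 0.00155; adjusted p = 0.392 with an estimated correlation; exact permutation p = 0.0857). Kcne1 stood at -0.34, the water channel Aqp3 at -0.25, Tspan1 at -0.15 and Scnn1b at -0.15. Kcne1 was dim, at 3.04 in wild-type arrays. The list shares Calb1 with DCT calcium handling, and Scnn1b, Scnn1g and Hsd11b2 with the aldosterone and glucocorticoid targets. Its shift therefore need not come from other cell types. This call was lost without TBC1D4-deficient replicate 3 (-0.0787, adjusted p = 0.0723) and within arrays 9 to 12 (-0.0795, against -0.182 within 5 to 8). Immune cell markers were higher in 13 of 18 genes, by a mean of 0.0685 (camera adjusted p = 0.0232; adjusted p = 0.547 with an estimated correlation; exact permutation p = 0.171). Cx3cr1 stood at 0.28, C1qb at 0.17, Fcer1g at 0.14 and Tyrobp at 0.10. All were dim, at 3.16, 2.48, 3.41 and 2.18 in wild-type arrays, where a level cannot be told from background. Leaving out TBC1D4-deficient replicate 2, 3 or 4 or wild-type replicate 1 ended this call with means of 0.0563 to 0.0679, and leaving out wild-type replicate 4 did so at 0.0438 (adjusted p = 0.157). The call also ended within arrays 5 to 8 (0.0359, adjusted p = 0.38, against 0.101 within 9 to 12).

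Markers of fibroblasts, mesangial cells and smooth muscle were lower in 11 of 14 genes, by a mean log2 difference of -0.0675 (camera adjusted p = 0.0283; adjusted p = 0.588 with an estimated correlation; exact permutation p = 0.2). Col1a2 and Rgs5 stood at -0.22 each, Acta2 at -0.22 and Gata5 at 0.23. Col1a2, Rgs5 and Gata5 were dim, at 3.15, 2.92 and 2.90 in wild-type arrays. This call was lost without TBC1D4-deficient replicate 1 (-0.033, adjusted p = 0.778), wild-type replicate 1 (-0.075, adjusted p = 0.0575) or wild-type replicate 3 (-0.0402, adjusted p = 0.268), after renewed quantile normalization (-0.0527), and within either number set (-0.0542 and -0.0808). It was also lost with the proximal tubule marker mean (-0.0434, adjusted p = 0.201) or the identifier range (-0.0484, adjusted p = 0.207) as a covariate. No shift was called for the thick ascending limb (adjusted p = 0.428), intercalated cells (0.428), podocytes (0.891) or erythroid cells (0.817, with 3 genes measured) with all 8 arrays and the preset correlation. The intercalated cell list was called in 3 of 25 alternative settings (lowest adjusted p = 0.0022), with means that ran from -0.229 to 0.0494 over the settings, and -0.223 within arrays 5 to 8 against -0.0208 within 9 to 12. In the levels per array, 0 of 9 lists passed after adjustment, which 1 list alone could not do even at the smallest possible p.

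**Figure D3:**
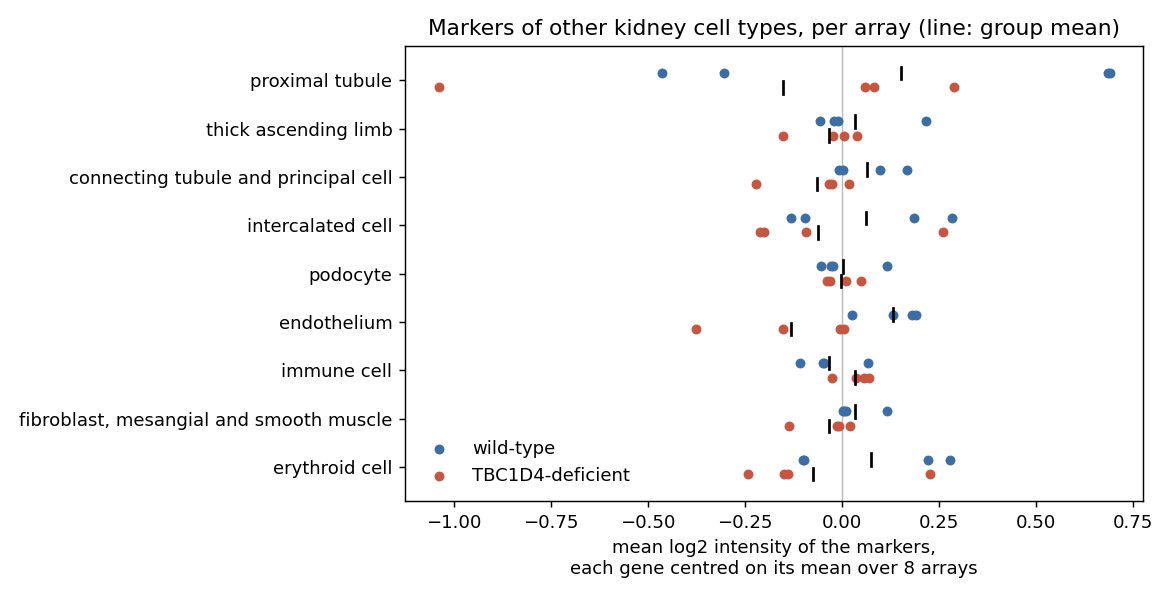
Each point is 1 array, with the mean log2 intensity of a cell type's markers, each gene centred on its mean over 8 arrays, on the horizontal axis and the 9 cell types on the vertical axis; blue is wild-type, red is TBC1D4-deficient, and lines mark group means. Only the endothelial markers do not overlap between the genotypes, with the highest TBC1D4-deficient array at 0.00579 and the lowest wild-type array at 0.025. The proximal tubule markers spread most, from -1.04 to 0.691.

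Genes beside Tbc1d4 on chromosome 14 were compared with the rest because a knockout line can carry flanking chromosome from another strain. Of 26 measured genes within 10 Mb, 2 (7.69%) had an unadjusted p below 0.05, against 548 of 18755 others (2.92%), an odds ratio of 2.77 (95% interval 0.316 to 11.2; Fisher's exact test, p = 0.176; camera p = 0.57). These were Commd6, the next measured gene on one side of Tbc1d4, at 0.36 (0.22 to 0.50), and Spry2, an inhibitor of growth factor signalling, at 0.28 (0.08 to 0.47). Adjusted over the 26 genes alone, the limma p was 0.00459 for Commd6 and 0.149 for Spry2, and both were picked out after their values were seen. Within the number sets 5 to 8 and 9 to 12, Commd6 stood at 0.32 and 0.40. With a window of 20 Mb the odds ratio was 3.21 (0.996 to 8.02; Fisher's exact test, p = 0.0254), and without wild-type replicate 4 it was 4.57 for 10 Mb (p = 0.0164).

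**Figure D4:**
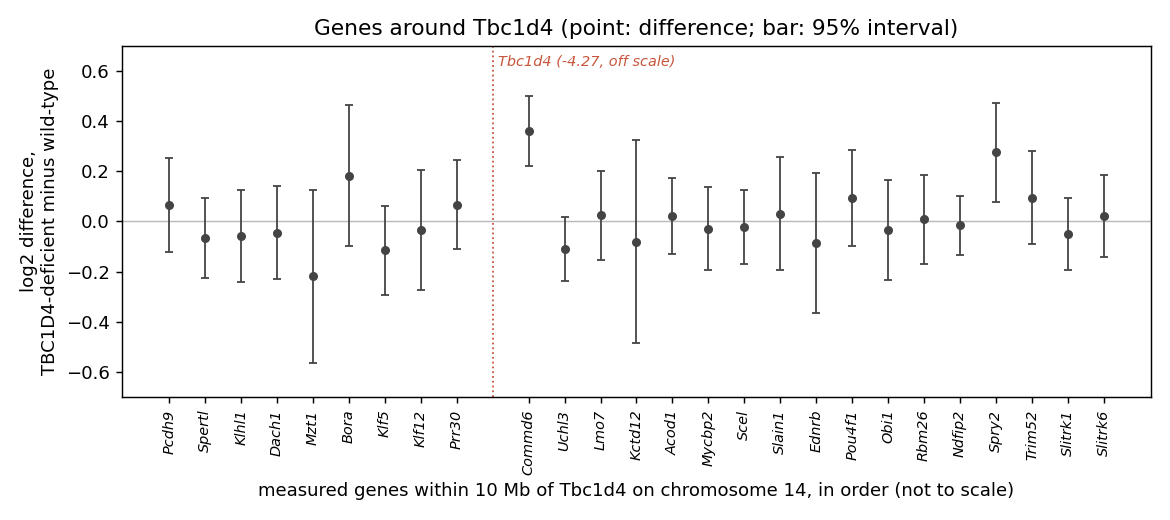
The log2 difference (TBC1D4-deficient minus wild-type, vertical axis) of the 26 measured genes within 10 Mb of Tbc1d4 is shown in chromosome order, not to scale, with bars for the 95% interval. Commd6, next to Tbc1d4, lies at 0.36, and the intervals of Commd6 and Spry2 exclude 0.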

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

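A sample far from the others of its genotype was found in 8 of 236 groups of 4 values, where chance gives about 11.8 (1 in 20), and none of these was weighed further. Among the named genes, Trip10 lay at 5.41 on the log2 scale in TBC1D4-deficient replicate 2, against 5.3 to 5.31 in the other arrays of its genotype. C1qb, a complement component of macrophages, lay at 2.21 in wild-type replicate 4, against 2.56 to 2.58.

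The other values are list means, with each gene centred on its mean over the 8 arrays. Wild-type replicate 2 stood above its group in sodium transport of the DCT (0.0455, against -0.0296 to -0.0204) and in the targets of aldosterone and glucocorticoids (0.139, against -0.0864 to -0.0735). TBC1D4-deficient replicate 1, the array with the lowest proximal tubule markers, stood below its group in glucose transporters (-0.166, against 0.0142 to 0.0275), a list that holds the proximal tubule genes Slc5a2 and Slc2a2. Wild-type replicate 3, the array with the highest proximal tubule markers, stood above its group in GLUT4 vesicle traffic (0.00778, against -0.00712 to -0.0051), in markers of the thick ascending limb (0.218, against -0.0562 to -0.0101) and in markers of fibroblasts, mesangial cells and smooth muscle (0.115, against 0.00271 to 0.0112).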

How the results depend on the processing

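Tbc1d4 was the only probe set past the threshold in all 25 alternatives for that count, with a log2 difference from -4.35 to -4.18 in the 23 that refit it. The smallest adjusted p of any other probe set was 0.349, with a trend and robust prior. In the levels per array, 0 marker lists passed in any of 11 alternatives. That says little, because even at the smallest possible p of 0.0286 the endothelial list reached only 0.257 after adjustment over 9 lists (exact permutation test). Within a number set, with 2 arrays against 2, the smallest possible p is higher still. No detection call was used, so what the arrays show of genes near background is limited.

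The number of lists past the threshold, 8, was 5 with the identifier range as a covariate and 0 with an estimated correlation, and ran from 5 to 10 when single arrays were left out. Over single lists and settings, 36 calls were lost and 19 gained in their own direction. The mean turned sign in 68 cases, 65 of them with no call on either side, in 16 lists. Those with a call were fatty acid oxidation and PPARA targets without wild-type replicate 1 (-0.00112), and, in the split added after the data were examined, cell cycle (-0.0102) and cholesterol and fatty acid synthesis (0.0729) within arrays 9 to 12. Left-out arrays moved the list of fatty acid oxidation from -0.00112 to 0.0937. The cause was not tested.

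The odds ratio of genes within 10 Mb of Tbc1d4 passed its threshold at 7.74 (Fisher's exact test, p = 0.0357) with a filter at the median intensity, at 3.21 (p = 0.0254) within 20 Mb and, in a covariate added after the data were examined, at 4.1 (p = 0.0452) with the proximal tubule marker mean. With single arrays left out it ran from 2.43 to 4.57, and passed only without wild-type replicate 4 (4.57; Fisher's exact test, p = 0.0164). The cause was not tested. With the replicate number as a block the odds ratio was 4.27 (Fisher's exact test, p = 0.041). Those numbers do not pair the samples: same-numbered arrays had residual correlations of 0.402, -0.189, 0.0391 and 0.0117, and 2 of 8 arrays correlated best with their own number. The block left 1 probe set and 8 lists past the threshold.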

Other observations

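The counts of splits for the calls, the gene lists and the genes near Tbc1d4 were set before their own outcomes were seen. They were not part of the plan fixed before the data were examined. The tests of calls and Commd6 with the proximal tubule covariate, and of Commd6 over the splits, were chosen after those patterns were seen but before their own outcomes. The tests on endothelial markers, flanking chromosome, first numbers, spread and whole chromosomes were chosen after the results were seen. Atf3, Fosb, Nr4a1, Ehd3 and Myo18b lie outside the rule for named genes and were picked after their values were seen. The largest difference between arrays followed the proximal tubule markers. The first principal component held 28.4% of the variance and followed the proximal tubule marker mean over the 8 arrays (Pearson r = 0.959, permutation p = 0.00012; Spearman rho = 0.976, permutation p = 0.00047; 1 relation tested; r = 0.896 without TBC1D4-deficient replicate 1 and wild-type replicate 3). It did not separate the genotypes (exact permutation p = 0.543).

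Immediate early genes, which dissociation of tissue induces, varied far more between wild-type than between TBC1D4-deficient arrays. Their list mean was 0.76, 0.238, -0.451 and -0.336 in wild-type replicates 1 to 4 and -0.142, -0.089, -0.000204 and 0.0211 in the TBC1D4-deficient ones, an SD of 0.56 against 0.0764. The SD was larger in wild-type for 20 of 23 genes, among them Atf3 (1.55 against 0.29), Fosb (1.24 against 0.19) and Nr4a1 (1.16 against 0.08). A permutation test of the spread gave p = 0.0286, the smallest possible. After adjustment over 28 lists, 3 of which reached that p, it was 0.267, so the difference in spread failed the correction. The test permuted distances from each genotype's own mean, so its p is only approximate. In wild-type replicates 1 to 4 the proximal tubule marker mean ran the opposite way, at -0.465, -0.305, 0.691 and 0.685. In TBC1D4-deficient replicates 1 to 4 it did not, at -1.04, 0.289, 0.0591 and 0.0824, with replicate 1 lowest in both lists. Clock genes, at 0.0861, 0.197, -0.194 and -0.121 in wild-type replicates 1 to 4, had an SD of 0.181 against 0.0443, and the cell cycle list the opposite order, 0.0968 against 0.197.

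The absence of calls beyond Tbc1d4 was weighed first. Of the 35 splits of the 8 arrays into 4 and 4, 4, the real one included, gave at least its 1 call, and the highest other split also had 1, so chance cannot be excluded for the count itself, although it concerns how many genes pass and not the 19.3-fold difference of Tbc1d4. With the proximal tubule marker mean as a covariate the count stayed at 1. That cannot tell whether carry-over from that segment hides other differences, because small changes of single genes would mostly be missed either way. In the simulated data, without that covariate, a 1.5-fold change of a gene changed alone passed in only 23.6% of cases. The split of the arrays into first numbers 5 to 8 and 9 to 12 gave 2808 probe sets (12.2%) at an unadjusted p below 0.05, against 1944 in the highest other split and 667 between the genotypes. It was looked up because it gave the most, so its rank of 1 of 35 carries little weight, but its match to the numbers in the labels is consistent with a technical step shared within each number set. The median intensities of whole arrays also parted by set, at 8.93 to 9.03 in arrays 5 to 8 and 8.41 to 8.77 in arrays 9 to 12. So did the second principal component (18.7% of the variance), at -13.1 to -1.51 and 1.44 to 18.8. Each set holds 2 arrays of each genotype and left Tbc1d4 as the only call, so this structure stays open as a source of noise and not of the genotype difference.

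Between these number sets, 1 of the 20 probe sets of Myo18b was lower by a log2 difference of -0.78 in arrays 9 to 12 and was the only probe set past the threshold (limma adjusted p = 0.0114). The cell cycle list was lower by a mean of -0.197 in arrays 9 to 12 (camera adjusted p = 4.24e-05, and 0.904 with an estimated correlation). Neither difference was corrected for the lower median intensities of arrays 9 to 12. Of the 35 splits, 7, the real one included, gave at least the 8 lists of the real split, with 9 in the highest other, and 5 likewise gave at least its odds ratio of 2.77 for genes within 10 Mb of Tbc1d4, with 4.88 in the highest other, so chance is not excluded for either result.

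Endothelial markers, none of which stands in another list, were the only cell type list without overlap between the genotypes. TBC1D4-deficient replicates 2 and 3 lay close to wild-type replicate 2. The brightest markers were Emcn (5.50 in wild-type, 5.05 in TBC1D4-deficient arrays) and Ehd3 (4.94 and 4.87). Leaving out TBC1D4-deficient replicate 1, the lowest array, kept a mean difference of -0.183, which argues against 1 array as the only source. Fewer contaminating cells of every kind stays open, as 7 of the 8 other marker lists were also lower in TBC1D4-deficient arrays. The endothelial mean minus the mean of those 8 differed by -0.167 (exact permutation p = 0.0571). It differed by -0.333 against immune cells and -0.197 against fibroblasts, mesangial cells and smooth muscle. These were the 2 lists with an exact permutation p below 0.05 (0.0286 each, 0.114 after adjustment over 8). The named immune markers, and Col1a2, Rgs5 and Gata5 of the other list, were dim. Such lists can miss a loss of their cells, so these 2 contrasts cannot tell the explanations apart. Against the proximal tubule the difference was 0.0389. Within genotypes the 13 markers varied together, with a mean pairwise residual correlation of 0.377 against a 95th percentile of 0.0938 for 10000 random lists of matched level. A varying amount of carried-over endothelium, despite the sort for fluorescent tubules, would give this, but the correlation does not single it out. Some lists without cell type markers also lay above 0.0938, such as oxidative phosphorylation (0.184) and cholesterol and fatty acid synthesis (0.601). Others lay below it, such as Rab GTPases (0.0227). That percentile was drawn for 13 genes at the level of the endothelial markers, so it is only a rough mark for other lists. A sparser capillary supply of the DCT in TBC1D4-deficient kidneys would look the same as carried-over endothelium and was not tested.

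The higher Commd6 signal beside Tbc1d4 was weighed last. Over all genes, 25 of the 35 splits, the real one included, gave a gene other than Tbc1d4 with a p as small, down to 4.08e-07, so chance cannot be excluded there. In an exact permutation count within 10 Mb, only the real split, 1 of 35, reached the limma p of Commd6 (0.000179, lowest other 0.00107). That count used 1 probe set per gene. A share of 1 of 35 is the smallest that 35 splits can give, with no correction for the other counts of splits. The count was also chosen after Commd6 had been seen, so it cannot exclude chance. With the proximal tubule marker mean as a covariate the log2 difference was 0.35, which argues against carry-over of that segment; other segments and endothelium were not tested for Commd6. Flanking chromosome of another strain, for which the odds ratio was 2.77 (0.316 to 11.2), and an effect of the altered Tbc1d4 locus on its neighbour cannot be told apart here. That interval is too wide to show or exclude an excess among the neighbours. On the whole of chromosome 14, 4.56% of 658 genes had an unadjusted p below 0.05 against 2.93% elsewhere (odds ratio 1.58, Fisher's exact test, p = 0.0195, 0.304 after adjustment over 20 chromosomes). Dpysl2 and Ang4, of the 19 other genes with the smallest unadjusted p, also lie on chromosome 14, more than 10 Mb from Tbc1d4. They were picked by these same p-values and were not tested apart.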
